A study of Homo sapiens with 16 samples.

How the data were processed

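UM-UC-3 and T24 are established human bladder cancer cell lines. The labels describe 16 samples, taken 48 h after transfection with 75 nM of either an siRNA against NAT10 or a control siRNA, and profiled by RNA-seq or by immunoprecipitation of RNA carrying N4-acetylcytidine (ac4C), called acRIP. NAT10 is the acetyltransferase that makes ac4C. The values used here came from UM-UC-3: 4 RNA-seq libraries (replicates 2 and 3 of each arm) and 4 acRIP peak lists (control and NAT10-si, in a first and a replicate round). The T24 libraries and the first UM-UC-3 RNA-seq pair were not analysed here. The sample descriptions name the replicate-round peak lists, and the arm and round of the first-round lists were known only from their names.

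Total RNA was extracted with Trizol and a column kit, per the labels' protocols, which name neither poly(A) selection nor rRNA depletion. The submitters' processing notes name bcl2fastq 2.19.1, HISAT2 2.1.0 and HTSeq 0.6.1 and the build hg19. The deposited expression table gave 1 value per gene and library and its header named no unit. The deposited values were read as FPKM, scaled by the authors to gene length and library size, because their columns summed to between 310508 and 319225 and the smallest steps depended on the gene. The peak caller is not given in the sources used here. Per the file headers, the authors gave each peak a fold enrichment (a ratio of immunoprecipitate to input), a p-value and log10 values of p and of the false discovery rate, named here as scores. The lists held 1 set of peaks per arm and round. Folds are the authors' own values and served only to describe, rank or filter peaks within a list. Peak coordinates are printed as the lists give them, counted from 1. Between 97.3% and 98.4% of peaks in a gene with a RefSeq entry overlapped that gene in GRCh38.p14, although the processing notes name hg19.

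The table held 58302 gene identifiers, of which 57532 were matched to a symbol. Values of 27560 of the 27571 genes above 0 in at least 2 libraries came out as whole multiples of 1 step per gene and library, within a relative tolerance of 4e-08. The smallest whole numbers that fitted gave 32755960 recovered reads in control replicate 2 and 17508797 in control replicate 3. They gave 16541721 in NAT10-si replicate 2 and 15748113 in NAT10-si replicate 3. A factor common to all values of a gene is lost, and genes above 0 in only 1 library were left out. The assigned reads may therefore be more. Replicates differed beyond sampling noise, with a mean chi-square per degree of freedom of 2.70 between control libraries and 2.54 between NAT10-si libraries. The main test had been planned for counts with a separate rule for normalised values, and that rule was used. It fitted limma-trend (limma 3.58.1, R 4.3.3) to log2(FPKM + 1) for the 14004 genes with a mean of at least 1 FPKM, with Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(FPKM + 1) scale and understate the change of low genes. The adjusted p of a gene comes from this limma fit unless another setting is named with it.

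Gene lists were fixed before the data were examined and covered 5 groups of DNA repair and damage signalling genes, p53 targets, replication, mitosis, ribosome biogenesis, ribosomal proteins, RNA modification, NF-kB targets, interferon-stimulated genes, the integrated stress and unfolded protein responses, sterol and fatty acid synthesis, glycolysis, oxidative phosphorylation, extracellular matrix, drug transport, apoptosis, Wnt and reported bladder cancer genes, histones, mitochondrially encoded genes and markers of other cell types. The 28 lists with at least 3 measured members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. An alternative estimated the correlation, where camera also uses the residual degrees of freedom of the 4 libraries and has little power. The replication list, with an estimated correlation of -0.018, went from an unadjusted camera p = 3.75e-18 to p = 0.00945. Not passing that alternative therefore does not show that a list did not move as a set. Named genes followed a rule also fixed beforehand: NAT10; the 10 largest increases and 10 largest decreases among genes past the threshold with a mean of at least 3 FPKM and arms that did not overlap; up to 4 members per list by p; and AHNAK, BCL9L, SOX4, AKT1 and THUMPD1. Some genes that the rule takes are not reported here. Lists of histones with polyadenylated forms, splicing factors, immediate early genes and intestinal mucosa genes were written after the data had been examined.

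Peaks overlapped if they shared at least 1 base on the same strand (bedtools 2.31.1). Genes in both control lists and neither NAT10-si list were called lost, genes in both NAT10-si lists and neither control list gained, and genes in all 4 lists kept. Shared genes and list members were compared by two-sided Fisher's exact tests over the tested genes. Expression changes of peak genes were set against 10000 random gene lists matched in 50 bins of mean expression, with p adjusted over the 4 sets. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

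The tests were tested on simulated data before use. In a simulation of NAT10-si against control over 13849 genes, limma found 84.4% of the genes changed 2-fold and 51% of those changed 1.41-fold, and called 11 of 13655 unchanged genes. The simulated dispersion was 0.001, the lowest value allowed, and noise in the data may be larger. Only 96 and 98 genes were changed, and genes varied independently of one another, so error rates in the data may be worse. Alternatives changed the pseudocount, the filter, the scaling, the test, the replicate block, the libraries, the peak threshold, the length of the lists and the overlap.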

Results

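RNA-seq and acRIP were used to ask how loss of NAT10 changes gene expression and the transcripts carrying ac4C in UM-UC-3 bladder cancer cells, in a study of cisplatin resistance and DNA repair. Expression was measured in 2 control and 2 NAT10-si libraries, with between 15748113 and 32755960 recovered reads. Peak lists came from 2 rounds with 1 list per arm. All expression values below are means ± SD of 2 libraries unless a library is named. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which may be technical.

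The first comparison asked whether the siRNA lowered its target and which genes changed with it. NAT10 mRNA fell from 18.3 ± 0.998 FPKM with control siRNA to 3.94 ± 0.140 FPKM with NAT10 siRNA. The control libraries held 19.0 and 17.6 FPKM and the NAT10-si libraries 4.04 and 3.84 FPKM. The log2 change was -1.97 with a standard error of 0.06 (limma adjusted p = 1.1e-04). Of the measured list members, 37 of 39 replication, 35 of 35 mitosis and 41 of 48 ribosome biogenesis genes fell, and 19 of 30 stress response, 17 of 31 interferon-stimulated, 18 of 25 NF-kB target and 10 of 11 histone genes rose. These 7 lists passed camera with the preset correlation and none with an estimated correlation (adjusted p between 0.151 and 0.319). Of 14004 genes tested, 7815 passed the threshold, 3904 higher and 3911 lower. A log2 change of at least 1 was met by 422 of the higher and 213 of the lower genes. The arms did not overlap for 80.4% of genes, against 33.3% by chance. Values correlated across genes at 0.993 between control replicates, 0.990 between NAT10-si replicates and 0.944 to 0.946 between arms.

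**Figure D1:**
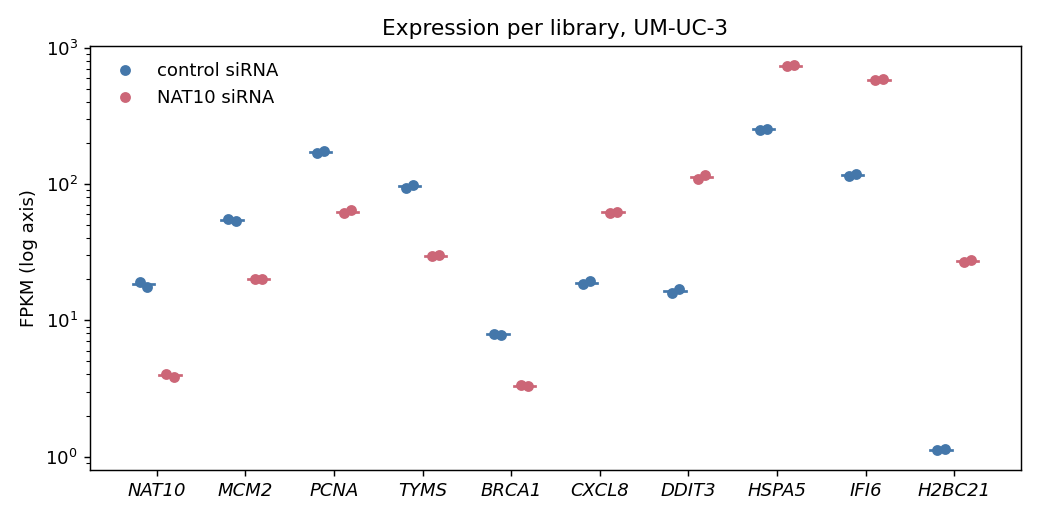
FPKM on a log axis for 10 genes in the 2 control (blue) and 2 NAT10-si (red) libraries, with points for libraries and lines for means. NAT10 fell from 18.3 to 3.94 FPKM and DDIT3 rose from 16.4 to 112 FPKM, with no overlap between arms in any gene shown.

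The 10 largest increases included histone genes. H2BC21, a histone H2B gene, rose from 1.13 ± 0.0226 to 27.3 ± 0.463 FPKM (limma adjusted p = 5.4e-05), and H2AC8 and H2BC7 rose by log2 values of 2.95 and 2.93. PER1, a clock gene, rose from 3.93 ± 0.0739 to 38.2 ± 0.815 FPKM. Outside these 10, DDIT3, which encodes the stress transcription factor CHOP, rose from 16.4 ± 0.671 to 112 ± 5.71 FPKM. The microRNA gene MIR616 lies within DDIT3 and its log2 change of 2.77 is uncertain, because reads of overlapping genes could not be told apart. The small nucleolar RNA genes SNORD14E and SNORD53 rose by 5.00 and 2.80 and lie in introns of host genes. The immunoglobulin genes IGKC, IGHA1 and IGHA2 were also among the 10 largest increases. IGKC was at 0.575 and 0 FPKM in the control libraries and at 20.5 and 5.56 FPKM in NAT10-si replicates 2 and 3. IGHA1 was at 0.154 and 0 against 18.9 and 4.17 FPKM, and IGHA2 at 0.134 and 0 against 18.1 and 3.40 FPKM. These genes are products of plasma cells, and their levels differed several-fold between both NAT10-si libraries. With no filter on low values, limma adjusted p was 0.0565 for IGHA1 and 0.0749 for IGHA2, and without control replicate 2 or 3 it was 0.0557 and 0.058 for IGHA2. Without NAT10-si replicate 2, 6777 genes passed the threshold. The largest decreases included NCOA5, a nuclear receptor coactivator, from 13.2 ± 0.819 to 2.07 ± 0.298 FPKM, and NAT10 itself. TFDP1, a partner of E2F factors, fell from 53.9 ± 0.923 to 14.3 ± 0.0348 FPKM. PPP1R10, FAM111B, GINS1 and TYMSOS fell by log2 values of 1.83, 1.74, 1.71 and 1.69. TYMSOS overlaps TYMS and MIR25 lies within MCM7, so their changes are uncertain, as is the fall of the mitochondrial tRNA gene MT-TQ.

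**Figure D2:**
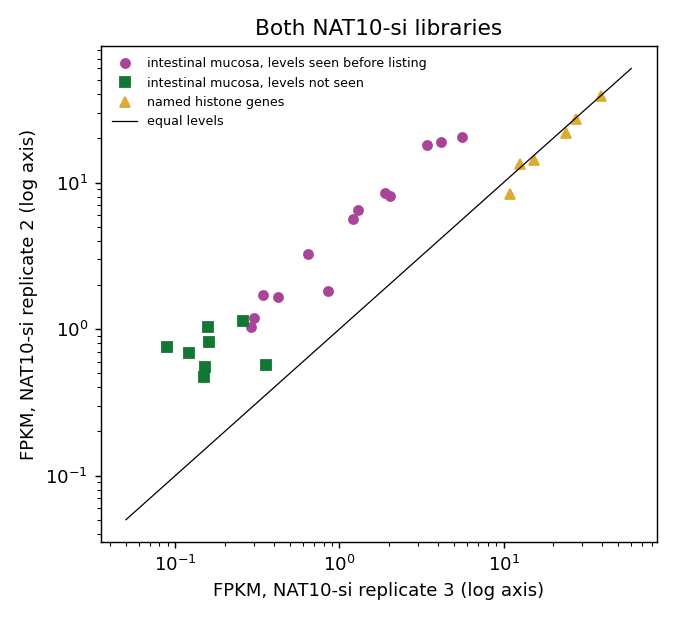
FPKM in NAT10-si replicate 2 against NAT10-si replicate 3, both on log axes, for 21 intestinal mucosa genes (circles and squares) and named histone genes (triangles), with a line at equal levels. The mucosa genes lay above the line, at a median ratio of 4.43, and the histone genes lay near it.

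Genes that copy DNA and divide cells fell together. Of 39 measured replication genes 37 fell and none rose, both over all genes and adjusted over the list alone, with a median log2 change of -1.03 (camera adjusted p = 1.0e-16; adjusted p = 0.151 with an estimated correlation). MCM2 and MCM4, subunits of the replicative helicase, fell by log2 values of 1.40 and 1.44, MCM4 from 57.0 ± 0.0701 to 20.4 ± 0.106 FPKM. PCNA, the sliding clamp, fell by 1.44, and TYMS, the thymidylate synthase, from 96.4 ± 2.99 to 29.8 ± 0.543 FPKM. All 35 measured mitosis genes fell, with a median of -0.77 (camera adjusted p = 2.4e-15; adjusted p = 0.151 with an estimated correlation). KIF11, a spindle motor, fell from 35.1 ± 0.904 to 11.6 ± 0.296 FPKM, and PLK1 and CCNA2 fell by log2 values of 1.12 and 1.23. Of 11 measured histone genes of the fixed list, 10 rose and none fell, with a median of 1.76 (camera adjusted p = 1.3e-06; adjusted p = 0.248 with an estimated correlation). H1-2, H2AC6 and H3C10 rose by 2.28, 1.76 and 2.69. In the same libraries the mitochondrial rRNA genes MT-RNR1 and MT-RNR2 and the nuclear RNAs MALAT1 and NEAT1, singled out after their values were seen, rose by 1.24, 1.35, 1.17 and 1.25.

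The title of the series names DNA repair, and repair genes were examined by pathway. Homologous recombination repairs double-strand breaks from a sister copy. Of its 37 measured genes 31 fell and 1 rose, with a median log2 change of -0.45 (camera adjusted p = 4.9e-08; adjusted p = 0.248 with an estimated correlation). BRCA1 fell from 7.88 ± 0.0310 to 3.31 ± 0.0418 FPKM, XRCC2 from 6.22 ± 0.244 to 1.78 ± 0.284 FPKM, and DNA2 and EXO1 by log2 values of 1.15 and 0.83. Of 27 base excision and mismatch repair genes 15 fell and 5 rose, with a median of -0.26 (camera adjusted p = 0.013; adjusted p = 0.288 with an estimated correlation). FEN1, a flap nuclease, fell from 45.4 ± 0.321 to 15.3 ± 0.158 FPKM, and UNG fell by 0.93. Of 25 damage signalling genes 14 fell and 3 rose, with a median of -0.33 (camera adjusted p = 0.00328; adjusted p = 0.320 with an estimated correlation). BRCC3, TIPIN and TIMELESS fell by 1.26, 1.08 and 0.88. Nucleotide excision repair removes bulky and cisplatin lesions. Of its 26 genes 12 fell and 3 rose, and the list did not pass the test (median -0.11, camera adjusted p = 0.0815). RPA1, which binds single-stranded DNA, fell by 0.97, and RPA2, LIG1 and RAD23B fell by 0.64, 0.57 and 0.32. Of 16 end-joining genes 8 fell and 1 rose, and the list did not pass (median -0.31, camera adjusted p = 0.0541). It passed without NAT10-si replicate 2 (adjusted p = 0.0436) and with voom on recovered reads (adjusted p = 0.0184), and not with an estimated correlation (adjusted p = 0.319). XRCC6 and PRKDC, parts of the DNA-dependent protein kinase, fell by 0.76 and 0.83, and POLQ and XRCC5 by 0.71 and 0.42. Adjusted over the list alone, 16 base excision and mismatch repair genes fell, and the other counts in these repair lists were the same.

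Genes for ribosome assembly fell and those for ribosomal proteins mostly rose. Of 48 ribosome biogenesis genes 41 fell and 3 rose, with a median log2 change of -0.55 (camera adjusted p = 4.5e-11; adjusted p = 0.221 with an estimated correlation). The nucleolar genes NCL, NOP56, NOLC1 and DDX21 fell by 0.96, 1.12, 0.89 and 0.99. Of 78 ribosomal protein genes 41 rose and 7 fell, with a median of 0.17 (camera adjusted p = 4.5e-04; adjusted p = 0.755 with an estimated correlation). RPS18, RPS21 and RPLP2 rose by 0.43, 0.42 and 0.36, and RPL17, which has many pseudogene copies, by 1.09. Of 29 genes of RNA modification, NAT10 among them, 16 fell and 2 rose, with a median of -0.24 (camera adjusted p = 0.00238; adjusted p = 0.319 with an estimated correlation). THUMPD1, the NAT10 adaptor for tRNA, fell from 5.55 ± 0.345 to 2.27 ± 0.0674 FPKM, and DKC1 and ALYREF fell by 0.69 and 0.81. Adjusted over the list alone, 43 ribosome biogenesis and 17 RNA modification genes fell, and the other counts were the same.

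Stress and inflammatory genes rose. Of 30 genes of the integrated stress and unfolded protein responses 19 rose and 2 fell, with a median log2 change of 0.63 (camera adjusted p = 2.8e-05; adjusted p = 0.319 with an estimated correlation). HSPA5, the chaperone BiP, rose from 252 ± 4.26 to 741 ± 6.06 FPKM, and HERPUD1 and SESN2 rose by 1.33 and 1.19. Of 25 NF-kB targets 18 rose and 2 fell, with a median of 0.57 (camera adjusted p = 2.8e-05; adjusted p = 0.288 with an estimated correlation). CXCL8, the neutrophil chemokine, rose from 18.9 ± 0.816 to 61.9 ± 0.758 FPKM, and LIF, NFKBIA and NFKBIZ by 1.75, 1.37 and 1.52. Of 31 interferon-stimulated genes 17 rose and 4 fell, with a median of 0.35 (camera adjusted p = 0.00199; adjusted p = 0.248 with an estimated correlation). IFI6 rose from 116 ± 2.60 to 584 ± 9.91 FPKM, and IFI27, BST2 and IFITM3 by 2.31, 1.91 and 1.06. Of 29 extracellular matrix genes 22 rose and 1 fell, with a median of 0.49 (camera adjusted p = 1.3e-06; adjusted p = 0.221 with an estimated correlation). MMP1, ITGA5 and CCN1 rose by 1.52, 1.13 and 1.00. Of 23 p53 targets 10 rose and 5 fell, and the list did not pass (median 0.18, camera adjusted p = 0.0541), but did with voom on recovered reads (adjusted p = 0.0184; adjusted p = 0.319 with an estimated correlation). GADD45A and TNFRSF10B rose by 1.59 and 0.82. Adjusted over the list alone, 18 interferon-stimulated genes rose and 5 fell, 23 extracellular matrix genes rose, and the other counts were the same.

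Metabolic genes moved in both directions. Of 23 sterol synthesis genes 13 rose and 8 fell (median 0.36, camera adjusted p = 0.102, 0.018 with voom on recovered reads and 0.320 with an estimated correlation), with MSMO1, HMGCS1 and INSIG1 higher by 1.32, 1.24 and 0.77. Of 17 fatty acid synthesis genes 2 rose and 8 fell (median -0.12, camera adjusted p = 0.135), with SCD, FADS1 and SREBF1 lower by log2 changes of -0.81, -0.61 and -0.52. Of 28 glycolysis and hypoxia genes 7 rose and 12 fell (median -0.10, camera adjusted p = 0.287), with PGAM1, LDHA, ENO1 and SLC2A1 at -1.15, -0.79, -0.66 and -0.66. Of 35 oxidative phosphorylation genes 12 rose and 7 fell (median 0.03, camera adjusted p = 0.377). Of 13 mitochondrially encoded genes 10 fell and 1 rose, with a median of -0.29 (camera adjusted p = 0.00165; adjusted p = 0.511 with an estimated correlation), and MT-CYB, MT-CO2 and MT-CO3 fell by 0.68, 0.56 and 0.45. Of 19 drug transport and cisplatin genes 5 rose and 6 fell (median 0.02, camera adjusted p = 0.999), with TXNRD1, GCLM and ABCC4 lower at -0.63, -0.79 and -0.42 and HMOX1 higher by 0.76. Of 26 apoptosis genes 7 rose and 12 fell (camera adjusted p = 0.797), with a median of -0.17 and a mean of 0.05. Adjusted over the list alone, 11 oxidative phosphorylation genes rose and 6 fell, and the other counts were the same. With no filter on low values the calls of MT-CYB, MT-CO2 and MT-CO3 were lost (limma adjusted p = 0.0543, 0.186 and 0.252). PMAIP1 and BIRC3 rose by 1.30 and 1.26, and RIPK1 and FADD fell by 1.17 and 0.82.

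Of 16 Wnt and reported bladder cancer genes 5 rose and 5 fell (median -0.13, camera adjusted p = 0.771). AHNAK, a large scaffold protein, fell from 100.6 ± 6.30 to 63.5 ± 4.76 FPKM (limma adjusted p = 0.0013). AKT1 fell from 17.8 ± 0.863 to 15.1 ± 0.594 FPKM (limma adjusted p = 0.022). SOX4 rose from 1.26 ± 0.125 to 1.92 ± 0.329 FPKM (limma adjusted p = 0.044). With no filter on low values adjusted p was 0.0637 for AKT1 and 0.147 for SOX4. The AKT1 call was lost without control replicate 2 or NAT10-si replicate 2 (adjusted p = 0.109 and 0.0928), and the SOX4 call without control replicate 2, control replicate 3 or NAT10-si replicate 2 (adjusted p = 0.182, 0.0996 and 0.144). BCL9L, a Wnt coactivator, was at 18.7 ± 1.28 and 16.7 ± 0.685 FPKM and did not pass (limma adjusted p = 0.097), but did with voom on recovered reads (adjusted p = 0.0181). CCND1, MYC and LRP5 changed by -0.94, 0.72 and 0.31. Few genes of the fixed marker lists of cell types were measured. Of 6 luminal urothelial genes KRT7 rose and KRT18 fell, with a median of 0.08 although camera put the list lower (adjusted p = 0.999). Of 6 basal genes 2 rose and 2 fell, with a median of -0.13 and a mean of 0.05 (camera adjusted p = 0.771). Of 4 endothelial genes EGFL7 rose, and none of 3 fibroblast genes passed. Of these 3, THY1 and COL3A1 passed with voom on recovered reads (limma adjusted p = 0.000854 and 0.0207), and THY1 also without NAT10-si replicate 2 (adjusted p = 0.0268). LCP1, the only measured gene of the fixed immune marker list, which held no immunoglobulin gene, rose from 0.842 ± 0.00749 to 3.86 ± 0.225 FPKM.

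**Figure D3:**
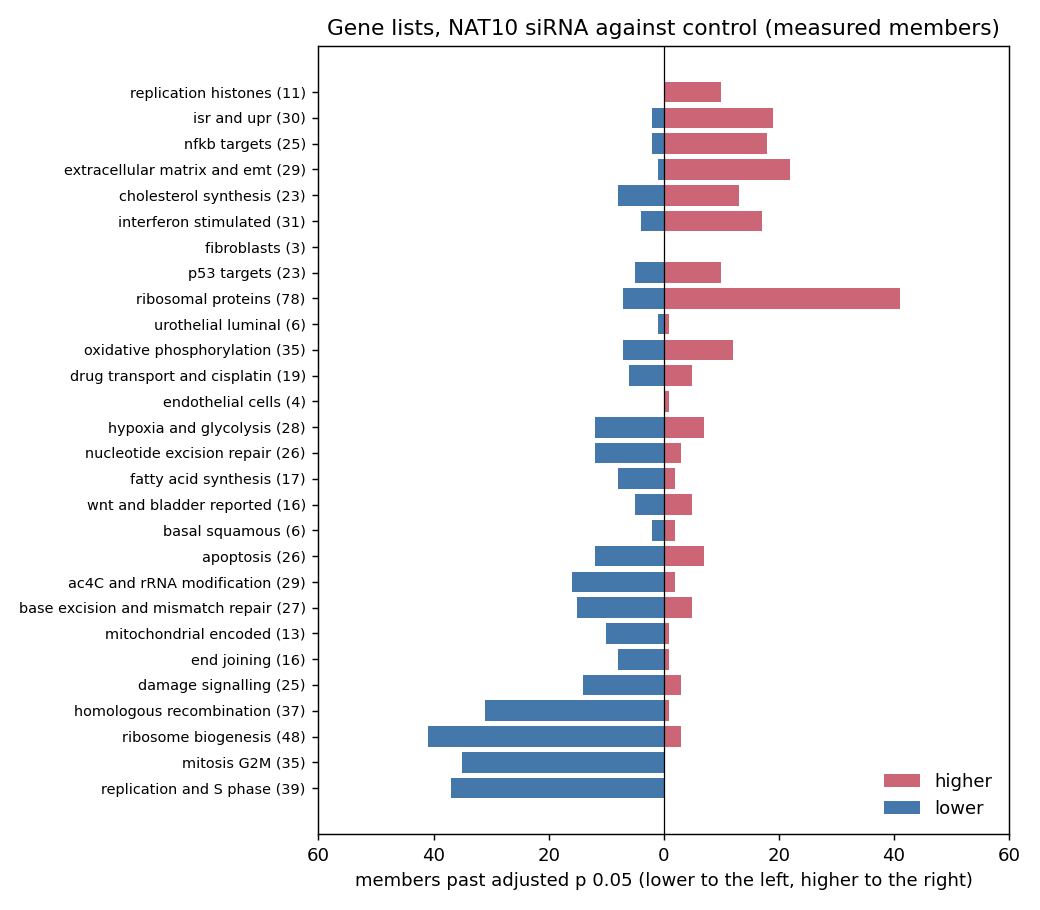
Number of members of each gene list past the threshold, lower to the left in blue and higher to the right in red, with measured members in parentheses. Of 39 replication genes 37 were lower, and of 30 stress response genes 19 were higher.

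The second comparison asked which transcripts carried ac4C and whether NAT10 siRNA removed the mark. In the first round the control list held 685 peaks in 620 genes and the NAT10-si list 666 peaks in 625 genes. In the replicate round the control list held 10253 peaks in 8057 genes and the NAT10-si list 16753 peaks in 11087 genes. Peaks covered 0.138 and 0.131 megabases in the first round and 2.29 and 4.42 megabases in the replicate round. The ratio of NAT10-si to control peaks was 0.972 in the first round and 1.63 in the replicate round. With 1 list per arm and round, this difference has no test. All first-round peaks and 8188 and 13113 of the replicate-round peaks were at a false discovery rate of 0.05 or less.

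**Figure D4:**
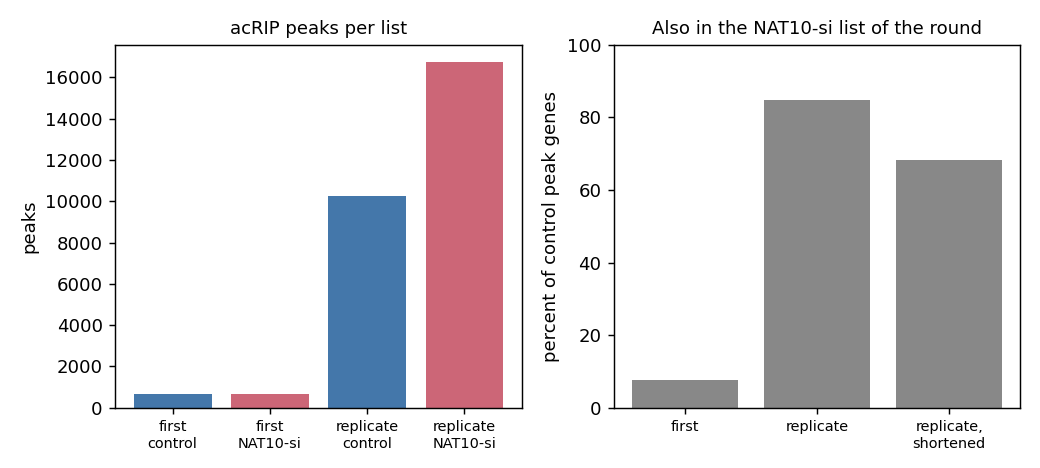
Left, number of peaks in each of the 4 lists, and right, percent of control peak genes also in the NAT10-si list of the same round, with replicate-round lists as given and shortened. The share was 7.7% in the first round, 84.7% in the replicate round and 68.3% after shortening. These shares are not set against chance, which is higher for long lists.

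Few peaks lay at the same place in both arms of the first round. There, 22 of 685 control peaks (3.2%) overlapped a NAT10-si peak, and in the replicate round 7575 of 10253 (73.9%) did. With lists of equal length the replicate-round share was 36.4%. Of the first-round control peaks, 41 (6.0%) overlapped a replicate-round control peak. Among tested genes the first-round arms shared 40 peak genes, against 14.8 by chance (two-sided Fisher's exact test, adjusted p = 1.1e-08). The replicate-round arms shared 6144 against 4483 by chance. The control lists shared 269 against 210.9 by chance, and the NAT10-si lists 383 against 314.8. These chance counts treat every tested gene as equally able to give a peak and were not matched on expression. In the replicate control list, for example, all 78 ribosomal protein genes had a peak, against 38.7 by chance. The excess of shared genes therefore need not be shared ac4C. The highest folds of the authors belonged to CD68, BANF1 and ENSG00000264772 in the first control list and to ERICH6B, MEGF11 and SCN3A in the first NAT10-si list. The peaks of CD68 and ENSG00000264772 lay at nearly the same place on the same strand, so they may be 1 signal. LINC01363, SNHG19 and COX6B1 led the replicate control list, and LENG9, LINC01363 and ST3GAL1-DT the replicate NAT10-si list.

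Genes with a peak in both control lists numbered 294, of which 24 were lost and 29 were kept in all lists. Genes with a peak in both NAT10-si lists numbered 412, of which 115 were gained. The replicate NAT10-si list was the longest, and with lists of equal length 10 genes were lost and 7 gained. Mitochondrially encoded genes were over-represented, with 8 of 13 members (MT-ATP6, MT-CO1, MT-CO2, MT-CO3, MT-ND1, MT-ND2, MT-ND4 and MT-ND6) against 0.25 by chance (two-sided Fisher's exact test, adjusted p = 5.5e-10). Against random lists matched on expression, 1.02 were expected (adjusted p = 0.0056), and with peaks at or above each list's median fold none of the 13 remained. The bins held equal numbers of genes, so the highest bin spanned a wide range of levels. MT-ND2 and MT-ND4, at 2753 and 6289 FPKM in control cells, had few genes of like level in it, so the matching may not remove the effect of abundance. In the replicate round's control list alone, 10 of 13 had a peak against 6.45 by chance (adjusted p = 0.104). Fatty acid synthesis genes had 3 of 17 (ACLY, FASN and SCD; adjusted p = 0.0547, and 0.358 against lists matched on expression). By Fisher's test they passed with peaks at a false discovery rate of 0.05 or less (adjusted p = 0.0382). They also passed in the replicate round's control list alone (14 of 17, adjusted p = 0.0249). Neither of these tests was matched on expression. In that list alone 10 lists passed, ribosomal proteins with 78 against 38.7 by chance (adjusted p = 4.2e-23), so abundance may account for such passes. The recombination, nucleotide excision, base excision and mismatch, and end-joining lists had no member with a peak in both control lists, where chance would give 0.711, 0.499, 0.519 and 0.307. In the replicate round's control list alone 21 of 37, 18 of 26, 16 of 27 and 10 of 16 had a peak, against 18.4, 12.9, 13.4 and 7.94 by chance (adjusted p between 0.101 and 0.58). Damage signalling had 2 of 25 in both control lists (AHNAK and MDC1; adjusted p = 0.631). Lost genes named by the rule included FASN, the fatty acid synthase, CHUK, an NF-kB kinase, PRR5, RMDN2, PGM2 and KCTD5. Gained genes included MTA1, WWC1, UBALD1, CSNK1G1, TTC38 and ARMCX3. In none of the lost genes named here did the control peaks of both rounds overlap. Of the gained genes named here, only ARMCX3 had NAT10-si peaks that overlapped between rounds. The replicate-round peak of PGM2 had a log10 false discovery rate of -1.13, which misses 0.05.

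AHNAK had a peak on chromosome 11 at 62517914 to 62518094 in the first control list and none in the first NAT10-si list. In the replicate round both arms had AHNAK peaks over nearly the same span. It ran from 62433872 to 62516325 in control and from 62433572 to 62516925 with NAT10 siRNA. Within these spans, which cross introns, the peaks covered 541 and 1441 bases. AKT1 had 1 peak at the same place in both replicate lists, on chromosome 14 at 104769349 to 104769618, and none in the first round. BCL9L had replicate-round peaks in both arms, at 118896125 to 118896455 in control. NAT10 had 2 peaks, both in the replicate NAT10-si list. SOX4 and THUMPD1 had none.

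The third comparison asked whether transcripts with peaks changed in level. Of 269 tested genes in both control lists 60 rose and 108 fell, with a median log2 change of -0.08 against -0.01 for random lists matched on expression (adjusted p = 0.056). Of 15 tested lost genes 10 fell and none rose, with a median of -0.29 (adjusted p = 0.0732). FASN fell from 60.03 to 40.2 FPKM, CHUK from 8.35 to 5.38 FPKM and BRIX1 from 13.1 to 10.4 FPKM. Of 99 gained genes 34 rose and 29 fell, with a median of 0.06 (adjusted p = 0.182), and ARMCX3 rose from 13.8 to 26.1 FPKM. Of 27 kept genes 7 rose and 11 fell (median -0.12, adjusted p = 0.182). By camera the genes in both control lists and the lost genes passed (adjusted p = 0.043 and 0.00513), and neither did with an estimated correlation (adjusted p = 0.17 for each). With peaks at a false discovery rate of 0.05 or less, the genes in both control lists, the lost and the gained genes passed (medians -0.082, -0.253 and 0.121, adjusted p = 0.0379 for each). Gained genes also passed with peaks at or above each list's median fold (median 0.172, adjusted p = 0.0264), and genes in both control lists and lost genes with no matching (adjusted p = 0.0136 and 0.0476). With the replicate round alone the lost and gained genes passed at medians of -0.176 and 0.061 (adjusted p = 0.000267 for each), and with the first round alone at -0.063 and -0.083 (adjusted p = 0.0181 and 0.0024), so the gained genes went opposite ways. A peak needs reads, so a gene that fell may be called lost, and one that rose gained, for that reason alone. Matching used the mean over both arms and could not remove this, so these p-values do not tie ac4C to transcript level.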

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

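All tests in this part were chosen after the result they bear on had been seen, except that on shortened lists. The ratio of NAT10-si to control peak numbers went opposite ways in the rounds, at 0.972 in the first and 1.63 in the replicate round. This difference was not tested.

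In the first acRIP round 7.7% of control peak genes were also in the NAT10-si list, and in the replicate round 84.7%. Among tested genes the arms shared 40 against 14.8 by chance in the first round, a ratio of 2.7. In the replicate round they shared 6144 against 4483, a ratio of 1.37. Long lists share many genes by chance, so the raw shares alone do not measure agreement. The shorter lists of the first round do not account for the difference in shares, since replicate-round lists of the same length still shared 68.3%. With peaks at a false discovery rate of 0.05 or less the replicate-round share was 86.7%. Those lists still held peaks in 6615 control and 9095 NAT10-si genes, enough to share many by chance. That filter therefore cannot decide whether a looser threshold accounts for the difference. First-round peaks may rest on few immunoprecipitated molecules: 31.2% and 22.4% lay in genes under 1 FPKM against 4.8% and 4.7% in shortened replicate-round lists, a smaller difference of 17.7 points. Shortening kept the peaks of lowest p, which may favour abundant genes. In the full lists the gap was smaller, with 68.8% and 77.6% of first-round peaks in genes of at least 1 FPKM against 88.0% and 85.1% of replicate-round peaks. A difference in the cells between rounds was not tested and stays open.

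Intestinal mucosa and plasma cell transcripts were above 0 in the NAT10-si libraries and near 0 in the control libraries, led by IGKC, IGHA1, IGHA2, PHGR1 and PIGR, at 20.5, 18.9, 18.1, 8.42 and 8.05 FPKM in NAT10-si replicate 2. Of 8 measured genes seen beforehand 7 rose, with a median log2 change of 2.31. The list held 36 genes, 13 of them chosen because their levels had been seen, and 1 gene of the 36 (VIL1) had a mean of at least 1 FPKM in control cells, while AQP8 and GUCA2B were at 0 in both NAT10-si libraries. Among the 8 usable genes whose levels had not been looked at, the ratio of NAT10-si replicate 2 to replicate 3 had a median of 4.77 (bootstrap interval 3.15 to 6.61), against 0.885 for 11 low histone genes. A response of the same size in both libraries would give a ratio near 1, so RNA or reads of another sample, in unequal amounts, is a candidate explanation, and a response of unequal size stays open.

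Histone genes rose while replication genes fell: 25 of 27 clustered histone genes rose, a count raised by a filter on the mean of both arms, which favoured low genes that rose. A rise only of those known to give polyadenylated forms does not account for this, since of 6 others with at least 1 FPKM in control cells 5 rose, with a median log2 change of 1.1 (bootstrap interval 0.762 to 2.15). More RNA with no or a short poly(A) tail in the NAT10-si libraries may contribute. To look at this, 126 genes named as small RNAs or mitochondrial rRNA were taken by symbol, in place of a first set picked partly for its rise. Their median log2 change was 0.56 (bootstrap interval 0.36 to 0.67, 48 higher and 11 lower), between the values set for and against this explanation. Many of the 126 bear pseudogene symbols, and the same filter on the mean of both arms applied, so this median cannot decide the question. A larger rise of genes with polyadenylated forms was not settled, since their median lay above the others by 0.425 (exact permutation test, two-sided, p = 0.108) and the order turned by ratio of mean FPKM, at 5.04 against 8.28. These last 2 explanations stay open, and no biological explanation beyond the siRNA arm was tested.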

How the results depend on the processing

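Median-of-ratios scaling, voom on recovered reads and peaks at a false discovery rate of 0.05 or less were chosen after seeing the data. NAT10 fell under every alternative run. The count of changed genes lay between 5615 and 8822 over the pseudocount, filter, scaling, voom, block and left-out libraries, and with a log2 change of at least 1 it was 635 (422 higher, 213 lower). The replicate block gave 7294 genes and, of the named genes, ended only the SOX4 call (adjusted p = 0.0757); deviations of same-numbered libraries correlated at 0.013, so the samples share only a number. Of 28 lists 14 passed; none did with an estimated correlation, 23 by directional fry and 28 by mixed fry, which asks another question: whether list genes changed at all, as 7815 of 14004 genes did, and not whether they changed more than other genes. Over named genes 1177 of 1257 alternative values kept their direction and side of the threshold, 76 lost the call, mostly to the log2 minimum, and none turned. Peak results moved more, and the cause was not tested beyond fewer peaks or lists. Peaks at or above the median fold gave 86 genes in both control lists, 70 gained and 2 kept, 0 enriched lists, and an expression change of gained genes of 0.172 (adjusted p = 0.0264). Equal length gave 36.4% overlap, 42 genes, 10 lost, 7 gained and 8 kept. A false discovery rate of 0.05 gave 2 enriched lists (mitochondrially encoded and fatty acid synthesis genes) and medians of -0.082, -0.253 and 0.121 for both-control, lost and gained genes (adjusted p = 0.0379 for each). No matching gave -0.082 and -0.292 (adjusted p = 0.0136 and 0.0476), and camera the same medians (adjusted p = 0.043 and 0.00513; adjusted p = 0.17 for each with an estimated correlation). With 1 round left out, genes with an acRIP peak ranged from 620 to 8057, lost genes from 572 to 1230, gained genes from 577 to 4260, kept genes from 48 to 6827, overlap from 3.21% to 73.9%, the ratio of peak numbers from 0.972 to 1.63, and lists past the threshold from 1 to 10, where the 10 of the replicate round included histones with fewer peaks than by chance and left out the mitochondrially encoded genes. The expression change of peak genes then ranged from -0.063 to -0.013, the expression change of lost genes from -0.176 to -0.063, the expression change of gained genes from -0.083 to 0.061 and the expression change of kept genes from -0.053 to 0.008. The ratio of peak numbers, the gained median (-0.083) and the kept median (0.008) changed direction in 1 round. The lost and gained genes passed in each round alone, the kept genes in the replicate round (adjusted p = 0.000267) and the genes with a control peak in the first round (adjusted p = 0.0181). The value 0.000267 is adjusted from the smallest p that the random lists can give. The count-based normalisations, filters and tests planned for counts, and gene sets from matched coordinates, were not run.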

Other observations

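Both gene groups in this part were chosen, and all of its tests made, after the data had been examined and some members had been seen among the changed genes. Immediate early genes, which respond within minutes to stimuli, were higher after NAT10 siRNA: 28 of 34 measured genes rose and 2 fell, with a median log2 change of 0.91. DUSP1 and DUSP5, phosphatases of MAP kinases, rose from 69.0 to 317 FPKM and from 71.2 to 347 FPKM, and JUNB from 16.7 to 78.4 FPKM. Genes of RNA-binding and splicing factors were lower: 24 of 32 fell and 2 rose, with a median of -0.43. HNRNPM fell from 66.9 to 25.4 FPKM and SRSF3 from 37.3 to 13.0 FPKM, while SRSF5 rose from 41.4 to 54.7 FPKM.

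The hypothesis that these groups moved as sets was tested with camera. It gave p = 4.76e-11 for immediate early genes and p = 6.22e-07 for splicing factors with the preset correlation, and p = 0.109 and p = 0.207 with an estimated correlation. The larger p-values may come from the estimated correlation or from the few residual degrees of freedom that camera then uses. They do not decide whether either group moved as a set, and members picked after being seen lean toward a low p. The 8 histone genes with polyadenylated forms all rose, with a median log2 change of 1.98.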
